A study of Mus musculus with 15 samples.

How the data were processed

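The series holds 15 mouse C57BL/6 samples from the medial cortex at embryonic day 11.5. Of these, 12 are bulk RNA libraries made, per the labels' protocols, with a modified smart-seq2 method, which amplifies full-length cDNA from small inputs. Cells had been sorted with annexin V, which binds phosphatidylserine on the outer face of the cell membrane, and propidium iodide (PI), which enters cells whose membrane is broken. The labels put 6 libraries in the AnnexinV-positive PI-negative group and 6 in the group negative for both stains, called double-negative here, and number them 1 to 6 in each group. The other 3 samples carry no sort label and are not analysed here.

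The count table holds 55367 gene symbols and 12 libraries, and its deposited values are estimated counts: 8.84% of the nonzero values were not whole, and these values held 17.1% of all counts. The file calls them raw counts, and the design fixed before the data were examined assumed whole raw counts, so the values were rounded to whole numbers before every count test. A second deposited table is named TPM, but its columns sum to between 764764 and 1835680 and not to 1000000, so it was treated as a score per gene with no fixed total, and it entered alternative fits only. Per the submitters' processing notes, Trimmomatic, STAR, featureCounts and Seurat 4 were used and the builds GRCm38 and mm10 apply, with no role given for any of them. The tool that gave fractional counts, the gene annotation, the strand setting and any filter are not given in the sources used here. Counts of near-identical gene copies, of overlapping genes and of antisense pairs are therefore uncertain. No unique molecular identifiers are mentioned, so intervals and zero-count limits cover counting error only.

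Gene positions come from GENCODE M21 on GRCm38, in which 53292 of the 55367 symbols were found. Total counts per library ran from 88193 to 444412, with a median of 304626. On total counts, a single count was worth 2.25 counts per 1000000 counts (CPM) in the deepest library and 11.3 CPM in the shallowest. On the scale of the CPM values printed below, it was worth 2.41 CPM in the deepest (AnnexinV-positive library 5) and 15.4 CPM in the shallowest (double-negative library 3). Nothing in the labels says whether libraries of a group came from separate embryos or sorts, so p-values measure the spread between these libraries, which may be in part technical. No pair of libraries within a group was the same library sequenced again: chi-square per degree of freedom over genes lay between 4.50 and 21.1, where sampling noise alone gives about 1; this does not exclude separately amplified aliquots of 1 sample.

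The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with filterByExpr (minimum count 10, minimum total 15), TMM scaling, robust dispersion and the sort group as the sole term. It was two-sided, with Benjamini-Hochberg adjustment over the 3800 genes that passed the filter and a threshold of 0.05. Log2 fold changes are AnnexinV-positive minus double-negative, and their standard errors (SE) were taken as the fold change divided by the square root of the F statistic. CPM values are scaled with the TMM factors, and log2 CPM uses a prior count of 2. On 5 simulated data sets of 3800 genes with 6 and 6 libraries and 200 changed genes, this test found 9.80% of the genes changed 2-fold and 56.2% of those changed 4-fold. Of its calls there, 5.02% were false and 0 of the true ones had the wrong sign.

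The text names genes by a rule fixed before the data were examined. It takes the 12 genes with the largest log2 fold change in each direction among those past the threshold with a mean log2 CPM of at least 3 and a symbol that is not a predicted-gene or pseudogene name, up to 4 tested members of each list with the smallest p, and a fixed set of genes of cell competition, p53, apoptosis and cortical development. Genes named outside that rule are said to be so, and 1 gene of the fixed set is not reported here. A total of 29 gene lists with 499 entries was fixed at the same time, covering p53 targets, pro-apoptotic and anti-apoptotic genes, cell competition, WNT and YAP targets, MYC and ribosome biogenesis, progenitor, intermediate progenitor, neuronal, cortical hem, Cajal-Retzius and ventral forebrain markers, DNA replication, mitosis and DNA repair, blood, vessel, mesenchyme and macrophage markers, stress responses, hypoxia and glycolysis, engulfment, cholesterol synthesis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins and histones. For 20 entries the symbol was matched through older names in the RefSeq table of GRCm38.p6. The 20 lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over the lists), and again with an estimated correlation. The other 9 lists had too few members past the filter. For them the summed count per 1000000 counts outside haemoglobin genes and the rRNA gene CT010467.1 was compared with an exact permutation test adjusted over 9 lists, a test chosen after seeing the data (for the erythroid list, per 1000000 of all counts).

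Library measures (6 of them) were compared with two-sided exact permutation tests of the difference in means over all 924 assignments, whose smallest possible p is 0.00216, adjusted over the 6 measures. Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling, no filter, a filter of at least 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom with quality weights, limma on log2 of the deposited score table plus 1 or plus 0.1, the replicate number as a block, the set of replicate numbers (1 to 3 or 4 to 6) as a covariate, each set alone, fry in place of camera, and leaving out each library in turn. Chosen after seeing the data were fits without haemoglobin genes and the rRNA gene, without double-negative libraries 1 to 3, without double-negative libraries 3 and 5, and camera within each set of replicate numbers. Fits on fewer libraries applied the filter anew, so camera there could test other members of a list than the main fit did. List medians given for those fits cover members tested in the main fit.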

Results

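By its title, the study looks for superior and inferior neural progenitors in the mouse embryo. Here 12 bulk RNA libraries of sorted medial cortex cells were compared: 6 from cells that bound annexin V but excluded PI, and 6 from cells negative for both. Total counts were 88193 to 329813 in double-negative libraries and 190694 to 444412 in AnnexinV-positive libraries. The rRNA gene CT010467.1 took 21.5% to 43.6% of the counts of each library. Haemoglobin genes took 11.998% (95% exact binomial interval 11.9 to 12.1), 30.8% (30.6 to 30.9) and 12.3% (12.05 to 12.5) of the counts of double-negative libraries 1, 2 and 3, and at most 0.00964% in each of the other 9 libraries.

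**Figure D1:**
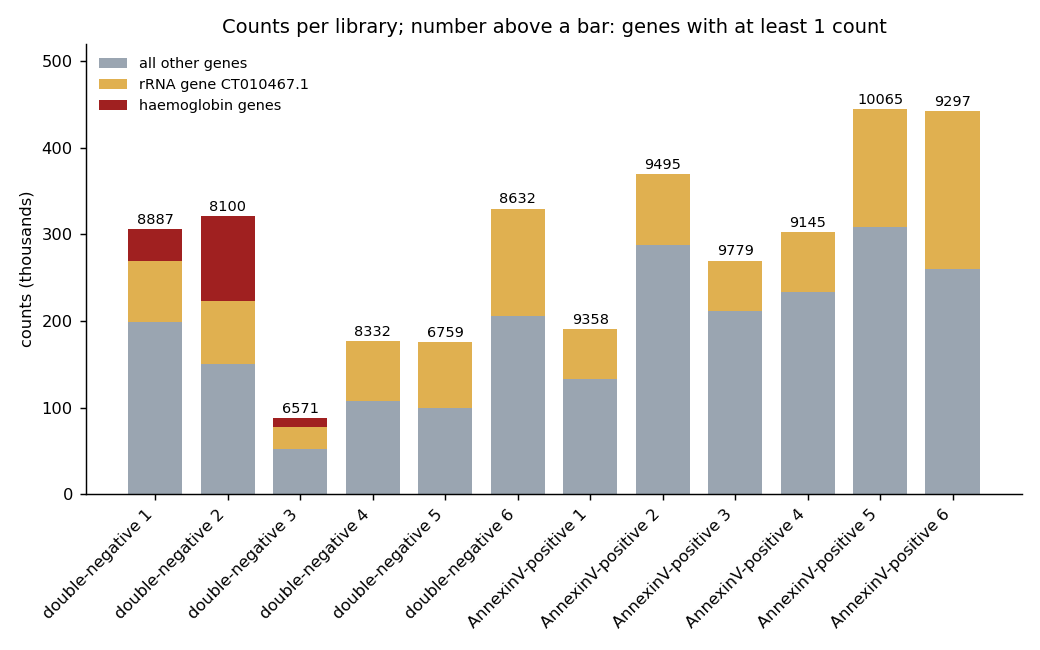
Counts per library (bar height), split into haemoglobin genes, the rRNA gene CT010467.1 and all other genes, with the number of genes with at least 1 count above each bar. Haemoglobin genes show in double-negative libraries 1 to 3 alone, and genes detected range from 6571 to 8887 in double-negative and from 9145 to 10065 in AnnexinV-positive libraries.

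The comparison of AnnexinV-positive with double-negative cells asks which genes go with annexin V binding while the cell membrane is still closed. Several genes of young neurons were lower in AnnexinV-positive cells. Stmn2, a microtubule regulator of growing axons, was at 23.9 ± 21.8 CPM (SD, n = 6) against 384 ± 198 CPM (SD, n = 6) in double-negative cells. Dcx, the doublecortin of migrating neurons, was at 82.0 ± 65.0 against 684 ± 202 CPM (SD, n = 6 each). Higher were, among others, Ccnd2 (cyclin D2) at 710 ± 200 against 215 ± 86.7 CPM and Mki67, a marker of cycling cells, at 499 ± 103 against 171 ± 98.9 CPM (SD, n = 6 each). For all 4 genes the libraries of the groups did not overlap.

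In all, 71 of 3800 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 15 higher and 56 lower in AnnexinV-positive cells. A raw p under 0.05 was found for 595 genes, where chance gives 190. Of the 3800 tested genes, 98 had no overlap between the libraries of the groups, which chance gives for 0.216% of genes. Upper-quartile scaling gave 42 higher and 55 lower genes in place of 15 and 56. Within replicates 1 to 3 alone 14 genes were higher and 56 lower, and within replicates 4 to 6 alone 1 was higher and 10 were lower. Only 2 genes passed in each set on its own, and the log2 fold changes of the sets had a correlation of 0.379 over 3273 genes. The count was 46 without double-negative libraries 1 to 3, 15 without double-negative libraries 3 and 5 and 126 without double-negative library 4.

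The 12 named genes with the largest increase in AnnexinV-positive cells had log2 fold changes from 1.27 to 3.35. Several belong to chromosome segregation and cell division: Knl1, a kinetochore scaffold (3.35, SE 0.84), Cenpf, a kinetochore protein (2.01, SE 0.46), Mki67 (1.51, SE 0.33) and Ccnd2 (1.70, SE 0.30). Eed, a subunit of Polycomb repressive complex 2, had 2.84 (SE 0.65), and Hmga2, a chromatin protein of early neural stem cells, had 2.14 (SE 0.46). The receptor Notch2 and the Hedgehog pathway transcription factor Gli3 rose by 2.16 (SE 0.48) and 1.80 (SE 0.38) on the log2 scale. Serp1, of the endoplasmic reticulum (2.28, SE 0.57), Gcsh, of the mitochondrial glycine cleavage system (2.22, SE 0.55), the mitochondrial chaperone Hspd1 (1.62, SE 0.33) and the peroxiredoxin Prdx1 (1.27, SE 0.30) complete the 12. Adjusted p in edgeR ran from 0.00214 for Ccnd2 to 0.0304 for Knl1, and each of the 12 was above the double-negative median in 6 of 6 AnnexinV-positive libraries. Knl1 had 15 counts in double-negative libraries, 12 of them in library 1, and lost its call in 14 of 26 alternatives. Serp1 and Gcsh lost theirs in 15 and 14 of 28 alternatives.

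The 12 named genes with the largest decrease had log2 fold changes from −5.35 to −3.12. Myt1l, a neuronal transcription factor, was the lowest (−5.35, SE 0.84, adjusted p = 0.000468 in edgeR). Dner, a Notch ligand of neurons (−4.20, SE 0.93), Ebf1, a transcription factor (−4.20, SE 0.97), and the transcriptional corepressor Runx1t1 (−4.05, SE 0.70) followed, with Stmn2 at −4.06 (SE 0.60). Ina, the neuronal intermediate filament internexin, had −3.87 (SE 0.79), the sodium channel gene Scn3a −3.43 (SE 0.64), and the RNA-binding protein gene Celf4 −3.15 (SE 0.42). The imprinted noncoding RNA Meg3 had −3.34 (SE 0.48), the ubiquitin ligase gene Hecw1 −3.51 (SE 0.84), Ank3 of the axon initial segment −3.13 (SE 0.63), and the phosphatase gene Dusp8 −3.12 (SE 0.82). All 12 were below the double-negative median in 6 of 6 AnnexinV-positive libraries. Of the 29 genes named in the text that passed, 13 lost the call when a single library was left out, 1 (Myt1l) passed in every alternative, and 0 changed sign in any. Of 809 alternative values of these genes, 221 no longer passed.

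**Figure D2:**
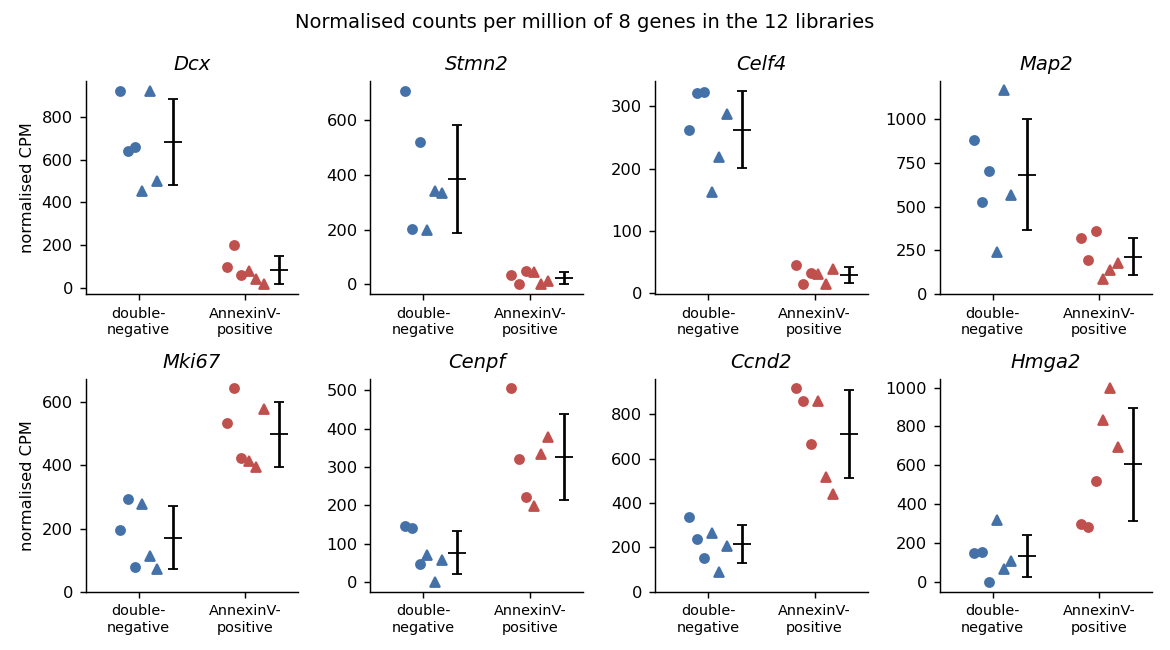
Normalised CPM of 8 genes (vertical axis, linear) in the 12 libraries, with circles for replicates 1 to 3, triangles for replicates 4 to 6 and bars for the mean and SD of 6 libraries. Dcx, Stmn2, Celf4 and Map2 lie lower, and Mki67, Cenpf, Ccnd2 and Hmga2 higher, in AnnexinV-positive libraries.

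On GRCm38, Stmn2 lies on chromosome 3 at 8509360 to 8561606, Dcx on chromosome X at 143855842 to 143933311, Ccnd2 on chromosome 6 at 127125162 to 127152193, Mki67 on chromosome 7 at 135689784 to 135716361 and Hmga2 on chromosome 10 at 120361275 to 120476469. All 5 are annotated as protein-coding genes.

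Neuronal markers fell as a group. Of 11 tested members 7 fell and 0 rose, 9 fell when adjusted over the list alone, and the median log2 fold change was −2.17 (camera adjusted p = 6.76e-18). This list passed with an estimated correlation too (adjusted p = 0.0193). Besides Stmn2, Dcx and Ina, the dendrite protein gene Map2 fell by 1.69 on the log2 scale (SE 0.35, adjusted p = 0.0102 in edgeR), while neuronal tubulin Tubb3 had −1.59 (SE 0.50, adjusted p = 0.101 in edgeR). The median was −1.93 within replicates 1 to 3 and −2.31 within replicates 4 to 6, so the difference was present both in the libraries with haemoglobin counts and in those without.

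Mitosis genes were higher as a group (median 1.34, camera adjusted p = 5.68e-09). Of 14 tested members, 14 had a positive sign, 2 rose (Mki67 and Cenpf) and 4 rose when adjusted over the list alone, among them Cenpe (1.72, SE 0.51) and Hmmr (2.61, SE 0.77), which had adjusted p = 0.0735 and 0.0774 over all genes in edgeR. The call was lost with an estimated correlation (adjusted p = 0.219 with an estimated correlation). The median was 0.77 within replicates 1 to 3 and 2.34 within replicates 4 to 6. Double-negative libraries 3 and 5, with the fewest detected genes, had the lowest list scores (4.12 and 3.65 mean log2 CPM, against 5.04 to 7.17 in the other double-negative libraries). The median was 0.89 without them and 2.81 without double-negative libraries 1 to 3.

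Cytosolic ribosomal protein genes all had a positive sign (39 of 39, median 0.58, camera adjusted p = 3.94e-08; adjusted p = 0.406 with an estimated correlation). Rps19 rose (0.96, SE 0.25, adjusted p = 0.0417 in edgeR) but lost its call in 17 of 28 alternatives. When adjusted over the list alone 13 members rose, including Rpl13 (0.94, SE 0.25) and Rpl30 (1.42, SE 0.40). The list of MYC genes and ribosome biogenesis was higher too (12 of 13 members positive, 0 past the threshold, 1 adjusted over the list alone, median 0.86, camera adjusted p = 0.00146; adjusted p = 0.249 with an estimated correlation). Its member Npm1, a nucleolar protein, had 0.84 (SE 0.26, adjusted p = 0.0898 in edgeR). Without double-negative libraries 1 to 3 the MYC list had a median of 0.88 and camera adjusted p = 0.0544.

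Radial glia and neural progenitor markers were higher as a list (13 of 17 members positive, 1 past the threshold, 7 higher when adjusted over the list alone, median 0.80, camera adjusted p = 0.000249; adjusted p = 0.249 with an estimated correlation). Hmga2 was the member that rose. Vim (1.11, SE 0.34), Notch1 (1.12, SE 0.35), Prom1 (1.67, SE 0.55) and Hes5 (1.53, SE 0.72) had adjusted p from 0.0926 to 0.297 in edgeR. The core progenitor factors Sox2 (−0.50, SE 0.40) and Pax6 (−0.03, SE 0.53) were not past the threshold, with adjusted p = 0.592 and 0.988 in edgeR. The list median was 1.26 within replicates 1 to 3 (camera adjusted p = 1.53e-06) and 0.29 within replicates 4 to 6 (0.147).

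DNA replication genes (median 0.74, 0 of 13 past the threshold and 0 adjusted over the list alone) had camera adjusted p = 0.00841, and adjusted p = 0.469 with an estimated correlation. Mcm3, of the replicative helicase, had 1.74 (SE 0.69, adjusted p = 0.198 in edgeR). Hypoxia and glycolysis genes (median 0.78, 0 of 9 past the threshold, 1 higher adjusted over the list alone) had camera adjusted p = 0.00599, and adjusted p = 0.460 with an estimated correlation. Gapdh, a glycolytic enzyme, had 0.78 (SE 0.26, adjusted p = 0.113 in edgeR). Within replicates 4 to 6 the replication list did not pass (median 0.36, camera adjusted p = 0.351), and without double-negative libraries 1 to 3 neither list passed (medians 0.27 and 0.50, camera adjusted p = 0.922 and 0.393). The replication call was lost in 6 of 23 alternatives and the hypoxia and glycolysis call in 3 of 23. For replication, camera adjusted p was 0.0799 without double-negative libraries 3 and 5, and up to 0.0875 without 1 library.

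**Figure D3:**
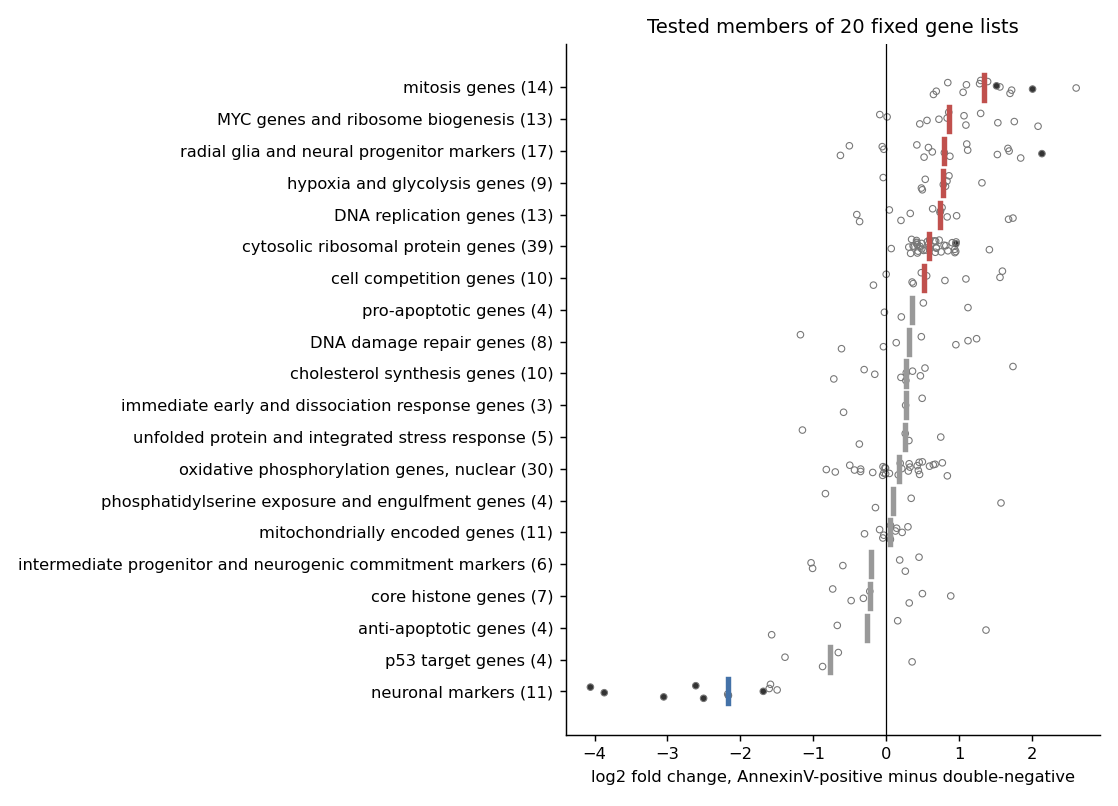
Log2 fold change (horizontal axis, AnnexinV-positive minus double-negative) of the tested members of 20 fixed lists, with the number of members in brackets; filled points passed the adjusted p of 0.05. Vertical bars are list medians, red (higher) or blue (lower) where camera with its preset correlation passed and grey where it did not; the neuronal list, at −2.17, is the single list lower.

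The transcription factor gene Trp53 did not pass (0.00, SE 0.74, adjusted p = 0.999 in edgeR), and the call for its target genes changed between fits and tests. Trp53 stood at 52.6 ± 21.6 CPM in AnnexinV-positive and 52.0 ± 25.7 CPM in double-negative libraries (SD, n = 6 each), and its inhibitor Mdm2 had a log2 fold change of 0.36 (SE 0.52). Of the p53 target genes 4 of 25 were tested and 0 passed, with a median of −0.76 (camera adjusted p = 0.371; adjusted p = 0.469 with an estimated correlation). The list was lower in 12 of 23 alternatives, 9 of them planned, among them fry (adjusted p = 0.0377) and fits without 1 library, and adjusted p ran from 0.00981 to 0.473 over all 23. Fits on fewer libraries applied the filter anew and may have tested other members than these 4. Their calls therefore cannot be laid to the libraries alone. The largest difference was Trp53inp1 (−1.39, SE 0.62, adjusted p = 0.265 in edgeR). The p53 effector Cdkn1a was below the filter: it had 1 count in the 6 libraries numbered 1 to 3, and 18, 10 and 146 counts in double-negative and 19, 5 and 84 counts in AnnexinV-positive libraries 4 to 6. Bax had 44 counts over the AnnexinV-positive and 24 over the double-negative libraries. These sums are not scaled for depth, and do not by themselves show a rise of Bax. Mean total counts were 336655 in AnnexinV-positive and 233115 in double-negative libraries. Bbc3 had 0 counts in the 12 libraries, which allows a share of up to 0.000675% in the deepest and 0.0034% in the shallowest.

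Pro-apoptotic genes (4 tested, 0 past the threshold and 0 adjusted over the list alone, median 0.36, camera adjusted p = 0.371) did not pass by camera, but were higher as a list by fry, a test fixed before the data were examined (adjusted p = 0.0248); the list passed in 1 of 23 alternatives. Anti-apoptotic genes (4 tested, 0 past the threshold, median −0.26, camera adjusted p = 0.930) went both ways: adjusted over the list alone, Birc5, which also acts in cell division, was higher (1.37, SE 0.51) and Bcl2l1, which encodes BCL-XL, was lower (−1.57, SE 0.55). Over all genes their adjusted p was 0.173 and 0.142 in edgeR.

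The list of cell competition genes was higher by camera (9 of 10 members positive, 0 past the threshold and 0 adjusted over the list alone, median 0.52, adjusted p = 0.0375; adjusted p = 0.219 with an estimated correlation). Its members with the smallest p were Tead1 (1.56, SE 0.53), Mycn (1.09, SE 0.52) and Yap1 (1.60, SE 0.79), with adjusted p of 0.127, 0.298 and 0.329 in edgeR. The list also holds Trp53 (0.00) and its inhibitor Mdm2 (0.36), so a higher list gives no direction of cell competition. Mycn is also in the MYC list and Mdm2 in the p53 list. The call was lost in 6 of 23 alternatives, with camera adjusted p up to 0.0895 without 1 library. It was 0.0799 without double-negative libraries 3 and 5 (median 0.32), 0.0915 within replicates 1 to 3 (median 0.88) and 0.0464 within replicates 4 to 6 (median 0.47). Myc was below the filter, with 25 counts in double-negative libraries, all in numbers 1 to 3, and 9 in AnnexinV-positive libraries. Of the WNT list, 2 of 15 members were tested. Ccnd1 (cyclin D1) had 2.06 (SE 0.58, adjusted p = 0.0648 in edgeR) and the WNT receptor regulator Znrf3 had 1.48 (SE 0.56, adjusted p = 0.183 in edgeR). Both were higher when adjusted over these 2 members alone. Axin2 was below the filter with 27 and 17 counts in AnnexinV-positive and double-negative libraries, not scaled for depth. Wnt3a had 0 counts in the 12 libraries.

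Intermediate progenitor markers did not differ as a list (6 tested, 0 past the threshold and 0 adjusted over the list alone, median −0.20, camera adjusted p = 0.229). Within replicates 4 to 6 alone the list had a median of −1.85 (camera adjusted p = 0.00272 with the preset correlation of 0.01). Over all libraries a correlation of 0.410 was estimated for it (adjusted p = 0.657 with an estimated correlation). Eomes had −0.59 (SE 1.08) and Neurog2 0.45 (SE 0.88), with adjusted p of 0.8289 and 0.840 in edgeR. Reln, of Cajal-Retzius cells, was the tested member of its list and had −3.08 (SE 1.19, adjusted p = 0.207 in edgeR). AnnexinV-positive library 4 held 33 of its 34 counts in that group, against 185 counts in double-negative libraries, and without that library Reln was lower (adjusted p = 0.000445 in edgeR), with 1 count left in its group. Gad2, of inhibitory neurons, was the tested member of the ventral forebrain list and had −3.03 (SE 1.01, adjusted p = 0.155 in edgeR). Its value was −3.86 within replicates 1 to 3, −1.48 within replicates 4 to 6 and −1.67 without double-negative libraries 1 to 3, and it passed in 6 of 28 alternatives.

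DNA damage repair genes (8 tested, 0 past, median 0.31, camera adjusted p = 0.647) held 1 lower member adjusted over the list alone, Trp53bp1 (−1.18, SE 0.33). The list named core histone genes, which also holds the linker histones H1f0 and H1f5, did not pass (7 tested, 0 past, median −0.22, camera adjusted p = 0.980). It held 1 higher and 1 lower member adjusted over the list alone, the variants H2az1 (0.89, SE 0.26) and H3f3b (−0.73, SE 0.21). Camera found no difference for the unfolded protein and integrated stress response (5 tested, median 0.26, adjusted p = 0.947), immediate early and dissociation response genes (3 tested, median 0.27, adjusted p = 0.930), phosphatidylserine exposure and engulfment genes (4 tested, median 0.10, adjusted p = 0.647), cholesterol synthesis genes (10 tested, median 0.27, adjusted p = 0.647), or nuclear oxidative phosphorylation genes (30 tested, median 0.18, adjusted p = 0.647). Mitochondrially encoded genes (11 tested, median 0.06, camera adjusted p = 0.930; adjusted p = 0.951 with an estimated correlation) had a median of 0.53 within replicates 1 to 3 (camera adjusted p = 0.0111) and −0.22 within replicates 4 to 6 (0.122). These within-set values use the preset correlation of 0.01, where 0.626 was estimated for this list over all libraries, and the difference between the sets was not tested for lists. In each of these 6 lists 0 members passed, over all genes or adjusted over the list alone.

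Markers of blood cells moved with the sort in libraries 1 to 3. Among the 71 genes, Prdx2 and Ftl1, which red blood cell precursors hold in large amounts and which were named after their values were seen, were lower in AnnexinV-positive libraries (−1.20, SE 0.26, and −1.10, SE 0.28). Mean Prdx2 was 2204 CPM in double-negative libraries 1 to 3, 1181 CPM in double-negative libraries 4 to 6 and 735 CPM in AnnexinV-positive libraries. Without double-negative libraries 1 to 3 their log2 fold changes were −0.63 (SE 0.26) and −0.33 (SE 0.26), with adjusted p = 0.337 and 0.719 in edgeR.

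AnnexinV-positive libraries held more detected genes, 9523 ± 341 against 7880 ± 980 (SD, n = 6 each; exact permutation test, adjusted p = 0.00649), without overlap. The share of counts in ribosomal protein genes was 2.25 ± 0.387% against 1.18 ± 0.278% (SD, n = 6 each; exact permutation test, adjusted p = 0.00649). This and the other shares here are of all counts, haemoglobin and rRNA included. All other genes took 46.9% to 65.0% of the counts in double-negative and 58.7% to 78.5% in AnnexinV-positive libraries. Shares of those other counts alone were not tested. The 50 highest genes of AnnexinV-positive libraries took 40.9 ± 6.71% of the counts, against 53.9 ± 5.49% in double-negative libraries (SD, n = 6 each; exact permutation test, adjusted p = 0.0173). These 50 include the rRNA gene, which took 21.5% to 43.6% of each library, and haemoglobin genes in double-negative libraries 1 to 3. The difference was not tested without those genes. Total counts (336655 ± 100871 against 233115 ± 99926.5), the mitochondrially encoded share (1.43 ± 0.128% against 1.07 ± 0.410%) and the haemoglobin share (0.00263 ± 0.00358% against 9.17 ± 12.1%) had adjusted p of 0.138, 0.101 and 0.165 (SD, n = 6 each; exact permutation tests). Within replicates 1 to 3 and 4 to 6, mean detected genes were 9544 against 7853 and 9502 against 7908, mitochondrially encoded shares 1.48% against 0.772% and 1.38% against 1.37%, ribosomal protein shares 1.90% against 1.09% and 2.60% against 1.28%, and shares of the 50 highest genes 37.8% against 55.3% and 44.0% against 52.5%; with 3 libraries a side the exact permutation test within a set cannot reach 0.05.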

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

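The test of neuron against progenitor content was chosen after its result was seen. The other tests of explanations in this part were written down before they were run. Several of them name patterns that had already been seen, so they were not fixed before the data were examined.

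Among 132 groups of 6 libraries examined for a library far from the rest, 8 stood out, and chance gives about 1 in 20 groups, or 6.6. The highest value stood apart for Myt1l (4.71 log2 CPM in AnnexinV-positive library 3, next 3.43), Dner (5.62 in AnnexinV-positive library 4, next 3.03), Reln (6.81 in AnnexinV-positive library 4, next 3.56) and the haemoglobin share among AnnexinV-positive libraries (0.00964% in library 3, next 0.00271%). The lowest value stood apart for Cenpf (3.03 in double-negative library 5, next 5.76), Trp53inp1 (3.03 in double-negative library 2, next 6.90), Tead1 (3.03 in double-negative library 3, next 5.60) and Hmmr (4.40 in AnnexinV-positive library 2, next 7.17). The value 3.03 is that of a gene with 0 counts in a library.

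A test of the difference of the sort effect between replicates 4 to 6 and replicates 1 to 3 passed for 3 of 3800 genes in edgeR, which lie outside the naming rule and are named after their values were seen, with 239 genes at a raw p under 0.05 where chance gives 190. Fth1 had a difference of 4.53 (SE 0.58, adjusted p = 0.000323 in edgeR) and Gpx1 one of 4.06 (SE 0.72, adjusted p = 0.0145 in edgeR). Their means in double-negative libraries were 3086 and 1772 CPM in numbers 1 to 3, which hold haemoglobin counts, and 203 and 155 CPM in numbers 4 to 6. Robo2, an axon guidance receptor, had a difference of −5.94 (SE 0.97, adjusted p = 0.00696 in edgeR): it was at 205 against 186 CPM in AnnexinV-positive and double-negative libraries 1 to 3, and at 2.63 against 183 CPM in libraries 4 to 6.

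Chance assignment of libraries to the groups is argued against as the origin of the 71 genes. Of 100 splits of the 12 libraries into 6 and 6, out of 462 possible, 1 gave as many genes. That was the real split, and the highest of the others gave 26. These splits treat the libraries as independent, which the labels do not state. A chance difference between a few embryos or sorts is therefore not addressed. The split by replicate set, 1 to 3 against 4 to 6, gave 6 genes.

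Neuronal markers were lower in AnnexinV-positive libraries, with a difference in list score (mean log2 CPM of the tested members) of −2.33 (SE 0.39; exact permutation p = 0.00216, n = 6 each, the smallest such a test can give). Red blood cells in double-negative libraries 1 to 3 are argued against as the whole cause, since within replicates 4 to 6 the score differed by −2.49 (SE 0.56). Library depth is argued against too, since after thinning every library to 52362 counts outside haemoglobin and rRNA the difference was −1.81 (SE 0.27). A gate that holds fewer neurons and more progenitors may account for the pattern: the progenitor list score was higher by 1.04 (SE 0.28), but by 0.58 (SE 0.45) within replicates 4 to 6, and Sox2 and Pax6 were not higher. A higher score was not particular to progenitors. Scores of pro-apoptotic (0.87, SE 0.30) and DNA damage repair genes (0.58, SE 0.20), which camera did not call, were higher too. Those of p53 targets (−0.44, SE 0.20) and intermediate progenitor markers (−0.57, SE 0.61) were lower. Fewer neurons and lower neuronal transcripts per cell thus cannot be told apart in bulk libraries, and a difference that comes with annexin V binding itself stays open and untested.

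Haemoglobin genes had 36741, 98872 and 10816 counts in double-negative libraries 1 to 3 and at most 26 in each other library. Whether the gate of numbers 4 to 6 or its tissue differed is not stated in the labels, and no explanation of these counts was tested.

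More genes were detected in AnnexinV-positive libraries (9523 against 7880). Total count is argued against as the whole cause, since thinning every library to 88193 counts left a difference of 935 genes (SE 275; exact permutation p = 0.0108, n = 6 each). After thinning to 52362 counts outside haemoglobin and rRNA the difference was 565 genes (SE 216; exact permutation p = 0.026, n = 6 each), so the counts taken by those genes could carry part of it. This thinning leaves those counts out, so they do not carry the difference of 565 genes that remains. By the bound set for this test the result is undecided, since 565 does not exceed 200 genes by 2 SE.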

How the results depend on the processing

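The count of 71 genes depended on the filter, the tool and the libraries. It was 237 with no filter, 164 with at least 1 CPM in 6 libraries and 268 with DESeq2, where 71 of the 71 genes passed. It was 40 on log2 of the deposited score plus 1, 20 with 0.1 in place of 1 and 21 with no filter on the score. Scaling with DESeq2 size factors gave 74, upper-quartile scaling 97, limma-voom 101 and the set covariate 100. Replicates 1 to 3 alone gave 70 and replicates 4 to 6 alone 11. Leaving out 1 library gave 49 (without double-negative library 3) to 126 (without double-negative library 4). Of the choices made after seeing the data, leaving out haemoglobin and rRNA genes gave 72, leaving out double-negative libraries 1 to 3 gave 46 and leaving out double-negative libraries 3 and 5 gave 15.

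Of 8 lists past the threshold, 1 passed with an estimated correlation, the neuronal list. With fry 8 passed, of which 6 were the same: DNA replication (adjusted p = 0.113) and hypoxia and glycolysis (0.0558) were lost, and p53 targets (lower, 0.0377) and pro-apoptotic genes (higher, 0.0248) were gained. Leaving out 1 library gave 7 to 11 lists. The p53 target list, not past in the analysis reported, passed as lower in 12 of 23 alternatives, 9 of them planned. In fits on fewer libraries the members tested may differ.

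The replicate block treats libraries with the same number as pairs. It gave 71 genes, 56 of them shared, and 8 lists. The labels do not say that the numbers mark a shared dissection or sort, so they were not used as pairs. Correlations of same-numbered libraries were −0.00694 to 0.0779, below the 0.1 required, and 3 of 12 libraries matched best with their own number. Between the sorts, mean correlations were 0.0385 for other numbers of the same set and −0.0394 for the other set. With 64 sign flips, whose smallest p is 0.03125, the differences of 1643 detected genes, −12.9 percentage points for the 50 highest genes and 1.07 percentage points for ribosomal protein genes had adjusted p of 0.0938, 0.125 and 0.0938. Counting genes with at least 10 counts gave a difference of 1527.5 (adjusted p = 0.0649, exact permutation test, n = 6 each). The mitochondrially encoded share differed by 0.261 percentage points without double-negative library 2 and 0.490 without double-negative library 5, where it passed (adjusted p = 0.00433, exact permutation test).

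Among the log2 fold changes of named genes the sign changed in 23 values, and none of these passed; medians of lists that did not pass are not counted here. Eomes (−0.59) had 0.48 without double-negative libraries 3 and 5. Trp53 (0.00) had −0.036 with DESeq2 size factors, −0.024 with DESeq2, −0.054 in replicates 1 to 3, −0.011 without haemoglobin and rRNA genes and −0.015 without double-negative libraries 3 and 5. Leaving out 1 library gave −0.22 (without double-negative library 6) to 0.15 (without double-negative library 2). Pax6 (−0.03) had 0.053 with upper-quartile scaling, 0.095 with no filter, 0.072 with the CPM filter, 0.49 on the score plus 1, with and without its filter, 0.52 on the score plus 0.1, 0.12 with the replicate block and 0.54 in replicates 1 to 3. Leaving out 1 library gave −0.35 (without AnnexinV-positive library 3) to 0.25 (without double-negative library 4).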

Other observations

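All tests in this part were chosen after the data were seen: they compare the summed count of a marker list per 1000000 counts outside haemoglobin and rRNA, over 9 lists whose members mostly lie below the filter, with an exact permutation test.

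The WNT feedback and target genes summed over the list were higher in AnnexinV-positive cells. The rise rests mainly on Ccnd1 and Znrf3, while Axin2 had 27 counts against 17 and Myc 9 against 25 (not scaled for depth). The sum of 15 genes was 610 ± 206 per 1000000 in AnnexinV-positive and 257 ± 127 per 1000000 in double-negative libraries (SD, n = 6 each; exact permutation test, adjusted p = 0.039), above the double-negative median in 6 of 6 libraries. The means were 565 against 200 in replicates 1 to 3 and 654 against 314 in replicates 4 to 6. Leaving out 1 library gave adjusted p from 0.039 to 0.0974. Ventral forebrain and interneuron markers were lower, at 157 ± 149 against 833 ± 653 per 1000000 (SD, n = 6 each; exact permutation test, adjusted p = 0.039, and 0.0195 to 0.0974 without 1 library). Most of the double-negative sum lay in replicates 1 to 3, with 1268 against 398 per 1000000 in replicates 4 to 6.

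Endothelial markers were higher in AnnexinV-positive libraries, with 432 counts against 4 (270 ± 369 against 6.01 ± 7.99 per 1000000, SD, n = 6 each; exact permutation test, adjusted p = 0.039). AnnexinV-positive libraries 5 and 6 held 165 and 235 of these counts, and the highest adjusted p without 1 library was 0.261. Pericyte and mesenchyme markers had 679 counts against 77 (adjusted p = 0.175, exact permutation test, n = 6 each), of which AnnexinV-positive libraries 3 and 6 held 218 and 312. Microglia and macrophage markers had 212 counts in AnnexinV-positive library 1 and 43 in double-negative library 1, and at most 10 in each other library (adjusted p = 0.648, exact permutation test, n = 6 each). These single libraries hold counts of other cell types that the labels do not mention.

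Cajal-Retzius markers had 133 counts in AnnexinV-positive and 355 in double-negative libraries, cortical hem and choroid plexus markers 215 and 108, YAP target genes 399 and 155, and erythroid markers 48 and 146907. Their adjusted p values were 0.175, 0.911, 0.175 and 0.212 (exact permutation tests, n = 6 each). The counts given here are not scaled for depth, whereas the tests used scaled sums.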
